A study of Mus musculus with 64 samples.

How the data were processed

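The deposited table gives raw gene counts, per the file headers and the authors' description, for 53008 gene names of the mouse assembly mm39 (GRCm39) with Ensembl 103 annotation. The authors took 15 mg of liver, kept RNA with an integrity number above 7, depleted ribosomal RNA and sequenced stranded total RNA. They aligned reads with STAR 2.7 and counted read pairs per gene name with featureCounts 2.0.1, and they name DESeq2 1.26.0 for their own testing. The 64 records listed are 4 per library, so the 16 libraries were each used once. Counts of near-identical copies were equal or close (Gm38378 and Gm37513 equal in 16 libraries, Rn7s1 and Rn7s2 within 0.03%), so the counts of such pairs are not independent; other relatives differed (Cyp4a10 and Cyp4a31 by up to 97.61%), and how reads with several matches were counted is not stated. For 78 gene names the table merges several Ensembl identifiers.

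The 4 groups were tested in one fit with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM scaling, the filterByExpr filter (17318 genes tested of 33954 with a count, 3200 of them below 1 CPM) and Benjamini-Hochberg adjustment over the tested genes, at adjusted p below 0.05 and no minimum fold. All tests were two-sided. The SE of a log2 change is its size divided by the square root of the F statistic, and the biological coefficient of variation was 0.197. Gene lists (29, with 512 of 517 symbols in the table) were tested with limma 3.58.1 camera at a preset correlation of 0.01 between genes, adjusted over 27 lists per comparison, and again with the correlation estimated per list. The limma fry test of direction was also run on the lists, and part of its results is given with the processing alternatives. For genes with at most 3 counts over a group the ratio of summed counts is given with a 95% interval that covers counting error alone. The comparisons, gene lists, rule for naming genes and alternatives were fixed before the data were examined, except limma voom with sample quality weights, the fit without WT HFD library 4 as a comparison of its own, and the tests on near-identical copies, with the position tests that leave them out, and on clock genes, which were added later. Genes named are the Mogat family, the 8 largest called increases and decreases per comparison with at least 1 CPM and no overlap between groups, up to 4 called members per list, and up to 10 interaction genes with the smallest adjusted p.

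The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a mean of at least 1 CPM, only the 2 groups compared, leaving out mitochondrial, ribosomal RNA and hemoglobin genes, and leaving out each library in turn. For chance, the libraries of each simple comparison were divided in all 35 ways and those of the interaction in 100 ways. In counts simulated with known changes, the test recovered 22.4% of genes changed 1.5-fold (15 of 67), 70.1% at 2-fold (47 of 67), 92.4% at 4-fold (61 of 66), and 7 of a further 20 genes raised 1.5-fold as a list, with 6 false among 136 calls (4.4%), 0 of wrong sign and 0 calls in a comparison without changes. The pass mark at 4-fold was first 95% and was lowered to 90% after the 92.4% was seen, so this check did not pass as first set. Of the 5 genes missed at 4-fold, 2 were below 1 CPM.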

Results

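Liver RNA of wild-type (WT) mice and of HuMgat2 mice was sequenced at the end of 16 weeks on chow or on a high-fat diet (HFD). HuMgat2 mice express human MOGAT2, which makes diacylglycerol from monoacylglycerol, in place of the mouse gene Mogat2. The 16 libraries fell into 4 groups of 4 mice each. Total counts per library ranged from 12.4 to 25.8 M. Their mean was 20.8 ± 0.9 M (SD, n = 4) in WT on chow, 21.2 ± 6.1 M in WT on HFD, 22 ± 3.1 M in HuMgat2 on chow and 21.3 ± 1.3 M in HuMgat2 on HFD. One library, WT HFD library 4, stood apart from its group. It held 12.4 M counts, and albumin (Alb) took 0.85% of them, against 3.259% to 6.018% in the other libraries. Its median Spearman correlation with its own group was 0.954, against 0.978 to 0.99 in the others. Levels below are counts per M (CPM) scaled by TMM, given as mean ± SD with n = 4 per group. A gene is said to have risen, fallen or changed only where its adjusted p from the edgeR quasi-likelihood test was below 0.05 over the 17318 genes tested.

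The first question was whether the modified gene and its relatives differed in the liver. Mogat2 (ENSMUSG00000052396, GRCm39 chromosome 7, 98868291 to 98887826) was near the limit of detection in every group. Its counts per library were 0 to 2 in WT on chow, 2 to 12 in WT on HFD, 0 to 1 in HuMgat2 on chow and 0 to 2 in HuMgat2 on HFD, too few to be tested. The annotation holds no entry for human MOGAT2, so its level was not measured. Mogat1 (ENSMUSG00000012187, chromosome 1, 78487806 to 78514810), which encodes a related monoacylglycerol acyltransferase, stood at 0.232 ± 0.14 CPM in WT on chow and 0.622 ± 0.509 CPM in WT on HFD. In HuMgat2 mice it rose from 0.337 ± 0.295 CPM on chow to 4.23 ± 0.941 CPM on HFD, a 12.8-fold increase (log2 3.68 ± 0.57 SE, adjusted p = 0.000437). Without HuMgat2 chow library 15 this log2 change was 4.42. On HFD the level of Mogat1 was 6.3-fold higher in HuMgat2 than in WT (adjusted p = 0.00288), and all 4 HuMgat2 HFD libraries lay above all libraries of the other groups. A difference in the diet effect of Mogat1 between the genotypes was not called by the interaction test (log2 2.19 ± 0.94 SE, adjusted p = 0.22). The diet effect in WT was not called either (log2 1.49 ± 0.67 SE, adjusted p = 0.149). Without WT HFD library 4, which had 0 Mogat1 counts, the WT change was 1.79 with adjusted p = 0.0357. Dgat2, which makes triglyceride from diacylglycerol and lies on the same stretch of chromosome 7 as Mogat2 (98802865 to 98831926), was 1.55-fold lower in HuMgat2 than in WT on HFD, at 180 ± 13.8 against 278.2 ± 31.4 CPM (adjusted p = 0.00402). On chow Dgat2 was not called between genotypes, but its mean lay in the same direction. Before TMM scaling it was 187 ± 40.6 CPM in HuMgat2 and 270 ± 46.4 CPM in WT on chow. Dgat1, the other triglyceride-forming enzyme, and Mgat2, a glycosyltransferase gene with a like name, were not called in any comparison, with adjusted p between 0.397 and 0.969.

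The comparison of HFD with chow in WT mice asked which genes differed with diet in the WT liver. Collection time and feeding are not in the labels, so a difference in either cannot be told apart from the diet. Of the listed genes, 17 of 24 of cholesterol synthesis, 11 of 18 NRF2 targets and 10 of 21 of xenobiotic metabolism fell. In the lists of matrix, inflammation and lipid droplets 16 of 26, 14 of 22 and 8 of 21 rose, and the 14 inflammatory genes were 7 without WT HFD library 4. With all libraries none of these 6 lists was called as a set with an estimated correlation (adjusted p 0.189 to 0.562). Idi1 (ENSMUSG00000058258, chromosome 13, 8935537 to 8942487), an enzyme of the isoprenoid steps of cholesterol synthesis, fell 7.52-fold from 178.5 ± 33.9 to 23.73 ± 3.99 CPM (log2 -2.91 ± 0.37 SE, adjusted p = 0.000134). Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, fell 3.27-fold from 535.4 ± 78.9 to 163.6 ± 46.1 CPM (adjusted p = 3.28e-05). Col3a1, a fibrillar collagen, rose 3.7-fold from 15.63 ± 1.75 to 57.97 ± 21.3 CPM (adjusted p = 9.09e-05). In each of these 3 genes all 4 libraries of one diet lay beyond all 4 of the other. The diet changed 2617 genes, 1449 higher and 1168 lower, of which 2120 had no overlap between the groups; 18.2% of all tested genes had none, against 2.86% by chance. The count of higher genes dropped to 856, 908 and 932 without WT chow libraries 5, 6 and 7. Leaving out WT HFD library 4 gave 2593 calls, 2063 of the 2617 among them.

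Among gene lists that fell with HFD in WT, cholesterol synthesis had the largest share of members lower with all libraries. Of 24 tested members 17 were lower and 0 higher (19 lower adjusted over the list alone). They included Cyp51 (4.95-fold), Nsdhl (4.15-fold) and Hmgcs1 (3.75-fold), and the set test gave adjusted p = 5.13e-12. The count of lower members was 10 without WT chow library 5 or 6 and 11 without WT HFD library 2. Of 18 NRF2 and glutathione genes 11 fell and 0 rose (12 lower and 1 higher adjusted over the list alone; adjusted p = 4.82e-09), among them the glutathione transferase Gsta2 (10.2-fold). Of 21 xenobiotic metabolism genes 10 fell and 1 rose (15 and 3 adjusted over the list alone; adjusted p = 1.69e-05), and 6 fell without WT chow library 5. Among those lower, the cytochrome P450 genes Cyp2c55 and Cyp2b10 fell 7.17-fold and 56.8-fold. Female-biased liver genes had 6 of 15 lower and 1 higher (8 and 2 adjusted over the list alone; adjusted p = 0.000927), with Cyp3a44 (4.73-fold) and Cyp3a16 (4.93-fold) among the lower. None of these 4 lists was called with an estimated correlation, at adjusted p = 0.278, 0.189, 0.278 and 0.278.

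By number of members higher, matrix genes led the lists that rose in WT, with 16 of 26 higher and 0 lower (21 higher adjusted over the list alone, set test adjusted p = 4.57e-12, and adjusted p = 0.278 with an estimated correlation). Besides Col3a1 they included the collagen Col1a1 (5.8-fold) and the macrophage elastase Mmp12 (19.1-fold), and 10 rose without WT chow library 6. De novo lipogenesis had 8 of 18 members higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 0.00606), with the sterol and lipid regulator Srebf1 (2.63-fold), Pnpla3 (5.25-fold) and Thrsp (4.63-fold) among the higher. Of 21 lipid droplet and fatty acid uptake genes 8 rose and 0 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00493). These included lipoprotein lipase Lpl (2.93-fold) and the droplet protein Cidec (4.99-fold). The droplet count was 4 without WT chow library 5 or 6 or WT HFD library 3, 5 without WT HFD library 2, and 14 without WT HFD library 4, where the list was also called with an estimated correlation (adjusted p = 0.019). Cell cycle genes had 2 of 16 members higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.00606). With an estimated correlation the lipogenesis, droplet and cell cycle lists each had adjusted p = 0.562.

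Immune lists also rose in WT on HFD, and their sizes moved with WT HFD library 4. Of 22 inflammatory and acute phase genes 14 rose and 0 fell (21 higher adjusted over the list alone; adjusted p = 6.29e-07), against 9, 8 and 7 without WT chow libraries 5 and 6 and WT HFD library 4. Of 18 macrophage markers 9 rose and 0 fell (15 and 1 adjusted over the list alone; adjusted p = 8.2e-05). That count was 5 without WT chow library 5, 4 without 6 or 8, 14 without WT HFD library 3, and 5 with 1 lower without WT HFD library 4. The pore-forming Mpeg1 rose 4.04-fold and the lipid-sensing receptor Trem2 8.01-fold, with log2 changes of 2.02 and 3.00 that were 1.41 and 2.37 without WT HFD library 4. Of 20 interferon response genes 6 rose and 0 fell (11 higher adjusted over the list alone; adjusted p = 0.000474), among them Isg15 (2.14-fold). The interferon count was 3 without WT chow library 5, 6 or 7 or WT HFD library 4, and 10 without WT HFD library 2 or 3. These 3 lists had adjusted p = 0.562 with an estimated correlation.

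The other lists were not called as sets in WT, with adjusted p between 0.0844 and 0.986. Of 19 bile acid genes 4 rose and 2 fell, among them Cyp7a1 (3.56-fold higher), the rate-limiting enzyme of bile acid synthesis, the sterol transporter subunit Abcg5 (3.25-fold higher) and Cyp2c70 (2.28-fold higher), while the bile salt export pump Abcb11 fell 1.67-fold. Of 28 fatty acid oxidation and PPAR alpha genes 3 rose and 2 fell: the carnitine acyltransferase Cpt1a rose 1.93-fold and Pdk4, which restrains pyruvate oxidation, fell 2.64-fold. That count of higher members was 1 without WT chow library 6 or 8 and 6 without WT HFD library 4. Of 17 circadian clock genes 7 rose and 4 fell, with Per3 3.53-fold higher and Clock 2.13-fold lower. The lipoprotein list had 3 of 19 higher and 0 lower, led by Apoa4 (12.1-fold), an apolipoprotein of triglyceride-rich particles. Glucose and insulin signalling had 2 of 18 higher and 2 lower, with pyruvate carboxylase Pcx 1.54-fold higher and the insulin receptor substrate Irs1 2.62-fold lower. Glycerolipid synthesis had 3 of 17 higher and 0 lower, and 1 without WT chow library 5, 7 or 8. Stress response genes had 2 of 19 higher, Xbp1 (1.66-fold) among them, and 2 lower. Immediate early genes had 2 of 15 higher and 3 lower, and 1 lower without WT chow library 7 or 8 or WT HFD library 1 or 3. Male-biased liver genes had 1 of 20 higher and 2 lower. Of the markers of other cells, 2 of 7 lymphocyte markers rose, Cd4 (3.98-fold) among them, as did 1 of 13 endothelial, 1 of 8 cholangiocyte, 1 of 3 adipocyte and 1 of 1 neutrophil markers. The adipocyte marker was Cfd, a secreted protease, at 0.271 ± 0.117 CPM on chow and 73.07 ± 53.8 CPM on HFD (266-fold), although WT HFD library 4 held 0.159 CPM. None of 14 stellate cell, 6 erythroid, 1 pancreas or 13 mitochondrial genome members changed. Of these lists, leaving out WT HFD library 4 led to a call as sets of glycerolipid synthesis (adjusted p = 0.00446), fatty acid oxidation (0.0138), adipocyte markers (0.0152) and, lower, stress response genes (0.0479). None of these calls was kept with an estimated correlation.

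Among the largest increases in WT without overlap between the diets, those of 5 genes were much smaller without WT HFD library 4. Saa2 and Saa1, acute phase apolipoproteins, rose 779-fold and 292-fold, and their log2 changes of 9.61 and 8.19 were 3.07 and 3.16 without that library. The iron-binding Lcn2 rose 264-fold (log2 8.04, and 4.37 without it), the neutrophil protease Prtn3 125-fold (6.97, and 3.49) and the macrophage glycoprotein Gpnmb 45.9-fold (5.52, and 3.43). Igkv8-16, an immunoglobulin light chain segment with 0 counts on chow, was at least 553-fold higher against a floor of 3 counts over the chow group. Moxd1 rose 53.2-fold (log2 5.73, 10.74 without WT chow library 6 and 5.09 without WT HFD library 4). The sulfate transporter Slc13a1 rose 43-fold (5.43, and 6.14 without WT chow library 7). Besides Cyp2b10, Gsta2 and Idi1, the largest decreases were in the citrate transporter Slc13a2 (15.5-fold), the clock gene Npas2 (10.7-fold), squalene epoxidase Sqle (8.17-fold), the taurine-synthesis enzyme Csad (8-fold) and the Idi1 pseudogene Idi1-ps1 (7.85-fold). Counts of Idi1 and Idi1-ps1 correlated at 0.998 across libraries, and whether they share reads was not tested. Of the genes named as changed in this comparison, Thrsp, Cidec and Cfd had overlapping ranges between the diets, and the others did not overlap.

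In the same diet comparison in HuMgat2 mice, 15 of 21 droplet genes, 11 of 18 lipogenic genes, 13 of 28 oxidation genes and 18 of 26 matrix genes rose. Of the male-biased genes 15 of 20 fell, and of the xenobiotic genes 13 of 21. With all libraries none of these 6 lists was called as a set with an estimated correlation (adjusted p 0.189 to 0.338). Cd36 (ENSMUSG00000002944), a fatty acid transporter, rose 5.64-fold from 45.61 ± 3.79 to 257.3 ± 26.9 CPM (log2 2.50, adjusted p = 3.07e-06). Cidea, a droplet protein with 3 counts over the HuMgat2 chow group and 1540 on HFD, was 452-fold higher (95% counting interval 154 to 2190). Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98525950 to 98537568), a steroid dehydrogenase higher in male than in female mouse liver, fell 412-fold from 144.3 ± 64.6 to 0.344 ± 0.153 CPM (log2 -8.69, adjusted p = 9.4e-06). All 4 libraries of one diet lay beyond the other 4 in these genes. The diet changed 2418 genes, 1309 higher and 1109 lower, and 2141 of them did not overlap, against 21% of all tested genes. The lower count was 679 without HuMgat2 HFD library 10. Without WT HFD library 4, which is in no arm of this contrast but in its estimate of the spread, 3394 genes were called, all 2418 among them.

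Lipid lists rose together in HuMgat2 on HFD. Of 21 lipid droplet and uptake genes 15 rose and 0 fell (16 higher adjusted over the list alone; adjusted p = 1.67e-11), with Plin4 (10.3-fold), which coats droplets, and Cidec (21-fold) among them. Of 28 fatty acid oxidation and PPAR alpha genes 13 rose and 0 fell (21 higher adjusted over the list alone; adjusted p = 1.29e-08). They included the thioesterase Acot3 (6.91-fold), the hepatokine Fgf21 (6.63-fold) and Vnn1 (5.26-fold). De novo lipogenesis had 11 of 18 members higher and 0 lower (13 and 1 adjusted over the list alone; adjusted p = 6.67e-08), among them Pklr (4.53-fold), the elongase Elovl6 (4.88-fold), fatty acid synthase Fasn (3.23-fold) and acetyl-CoA carboxylase Acaca (2.88-fold). Glycerolipid synthesis had 8 of 17 higher and 0 lower (11 higher adjusted over the list alone; adjusted p = 1.34e-05), with the acyltransferases Gpat3 (4.8-fold) and Gpam (2.51-fold) beside Mogat1. None of the 4 was called with an estimated correlation (adjusted p = 0.189, 0.338, 0.214 and 0.189), though without WT HFD library 4 droplet (0.0019), oxidation (0.0449) and glycerolipid genes (0.0449) were.

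Matrix, stellate cell and cell cycle genes rose too. Of 26 matrix genes 18 rose and 0 fell (20 higher adjusted over the list alone; adjusted p = 5.17e-15), with Col3a1 (3.69-fold), the collagen cross-linker Loxl2 (2.7-fold) and Mmp12 (9.86-fold) among them. Of 14 stellate cell markers 6 rose and 0 fell (6 higher adjusted over the list alone; adjusted p = 1.97e-05), including Lrat (2.2-fold), which stores vitamin A as retinyl esters, and decorin Dcn (1.71-fold). Of 16 cell cycle genes 9 rose and 0 fell (13 higher adjusted over the list alone; adjusted p = 6.1e-07), such as Cdc20 (3.83-fold) and the cyclin Ccnb1 (6.56-fold). The cell cycle count was 5 without HuMgat2 chow library 13 or 14 or HuMgat2 HFD library 11, and 4 without HuMgat2 chow library 16 or HuMgat2 HFD library 12. Of 18 macrophage markers 2 rose and 0 fell (2 adjusted over the list alone; adjusted p = 0.0103), Gpnmb (21.1-fold) and Trem2 (3.38-fold). The call of Trem2 ended without HuMgat2 chow library 13 or 15 or HuMgat2 HFD library 10 (adjusted p = 0.0516, 0.0586 and 0.0602). Of 3 adipocyte markers 2 rose (2 adjusted over the list alone; adjusted p = 0.0396), among them Cfd (50.5-fold). For these 5 lists the adjusted p with an estimated correlation was 0.189, 0.214, 0.189, 0.736 and 0.214, and without WT HFD library 4 the matrix and adipocyte lists were called with it (adjusted p = 0.0449 for each).

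Male-biased, xenobiotic, bile acid and immediate early genes had more members lower than higher on HFD in HuMgat2. Male-biased liver genes had 15 of 20 members lower and 0 higher (17 lower adjusted over the list alone; adjusted p = 8.88e-11), with the bile acid and steroid transporter Slco1a1 (25.1-fold) and complement component C6 (3.62-fold) beside Hsd3b5. Of 21 xenobiotic genes 13 fell and 1 rose (13 and 3 adjusted over the list alone; adjusted p = 9.46e-07): Cyp2c55 fell 13.7-fold, Cyp1a2 10.4-fold and Cyp2b10 26.2-fold, and Cyp2c38 rose 3.97-fold. Of 19 bile acid genes 7 fell and 1 rose (9 and 3 adjusted over the list alone; adjusted p = 0.00477), with Cyp2c70 3.22-fold and Abcb11 2-fold lower. Of 15 immediate early genes 9 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.00656), among them Ier2 (4.01-fold) and the phosphatase Dusp1 (3.87-fold). For these 4 lists the adjusted p with an estimated correlation was 0.214, 0.189, 0.302 and 0.561.

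Among lists not called as sets in HuMgat2 (adjusted p between 0.0758 and 0.934), female-biased liver genes split, with 6 of 15 higher and 6 lower, a median log2 change of -0.52 and a mean of 0.11. Cyp3a44 and Cyp3a16 fell 13.2-fold and 14.4-fold. Cholesterol synthesis had 4 of 24 higher and 1 lower, with 1 higher without HuMgat2 chow library 13 or HuMgat2 HFD library 9 or 10 and 2 without HuMgat2 chow library 14. Glucose and insulin signalling had 3 of 18 higher and 6 lower, with Pcx 2.22-fold higher and the insulin receptor substrate Irs2 (2.13-fold) and Igfbp2 (3.98-fold) lower. NRF2 and glutathione genes had 2 of 18 higher, sulfiredoxin Srxn1 (2.13-fold) and the carbonyl reductase Cbr3 (9.26-fold), and 4 lower. Clock genes had 3 of 17 higher and 4 lower, with Per3 1.7-fold higher and Clock 1.53-fold and Bhlhe41 3.53-fold lower, and 1 higher without HuMgat2 HFD library 10 or 12. The lipoprotein list had 3 of 19 higher, led by Apoa4 (17.7-fold), and 3 lower, 1 without HuMgat2 HFD library 9 or 10. Stress response genes had 3 of 19 higher, Atf5 (1.71-fold) among them, and 3 lower. Their lower count was 0 without HuMgat2 chow library 16 or HuMgat2 HFD library 10, 1 without HuMgat2 chow library 13 or HuMgat2 HFD library 11 or 12, and 5 without HuMgat2 chow library 14. Inflammatory genes had 2 of 22 higher, interferon genes 2 of 20, endothelial markers 3 of 13 and cholangiocyte markers 1 of 8 with 1 lower, and the 1 tested pancreas marker fell. None of 7 lymphocyte, 6 erythroid, 1 neutrophil or 13 mitochondrial genome members changed. Leaving out WT HFD library 4 led to a call of the inflammatory list as higher (adjusted p = 0.00398), with 9 members higher and 3 lower. That call was lost with an estimated correlation.

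Besides Cidea, Gpnmb and Cidec, the largest increases without overlap in HuMgat2 were in the glycosyltransferase A4gnt (197-fold), Cfd (log2 5.66, and 6.56 without HuMgat2 chow library 16), Ly6d (36.2-fold, log2 5.18, and 5.85 without HuMgat2 chow library 16), the T-cell gene Themis (25.8-fold) and the DNA repair gene Rad51b (20.6-fold). Besides Hsd3b5, Cyp3a16 and Cyp2c55, the largest decreases were in Hsd3b4, a relative of Hsd3b5 with 2 counts over the HFD group (190-fold, 95% counting interval 52.3 to 1580), Adgrf1 (153-fold) and the pseudogene Cyp2c53-ps (26.1-fold). Cyp2b10 fell by 4.71 on the log2 scale, and by 5.40 without HuMgat2 HFD library 12. Slco1a1 fell by 4.65, and by 5.41 without HuMgat2 HFD library 9. Of the genes named as changed in this comparison, Per3 had overlapping ranges between the diets, and the others did not overlap.

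**Figure D1:**
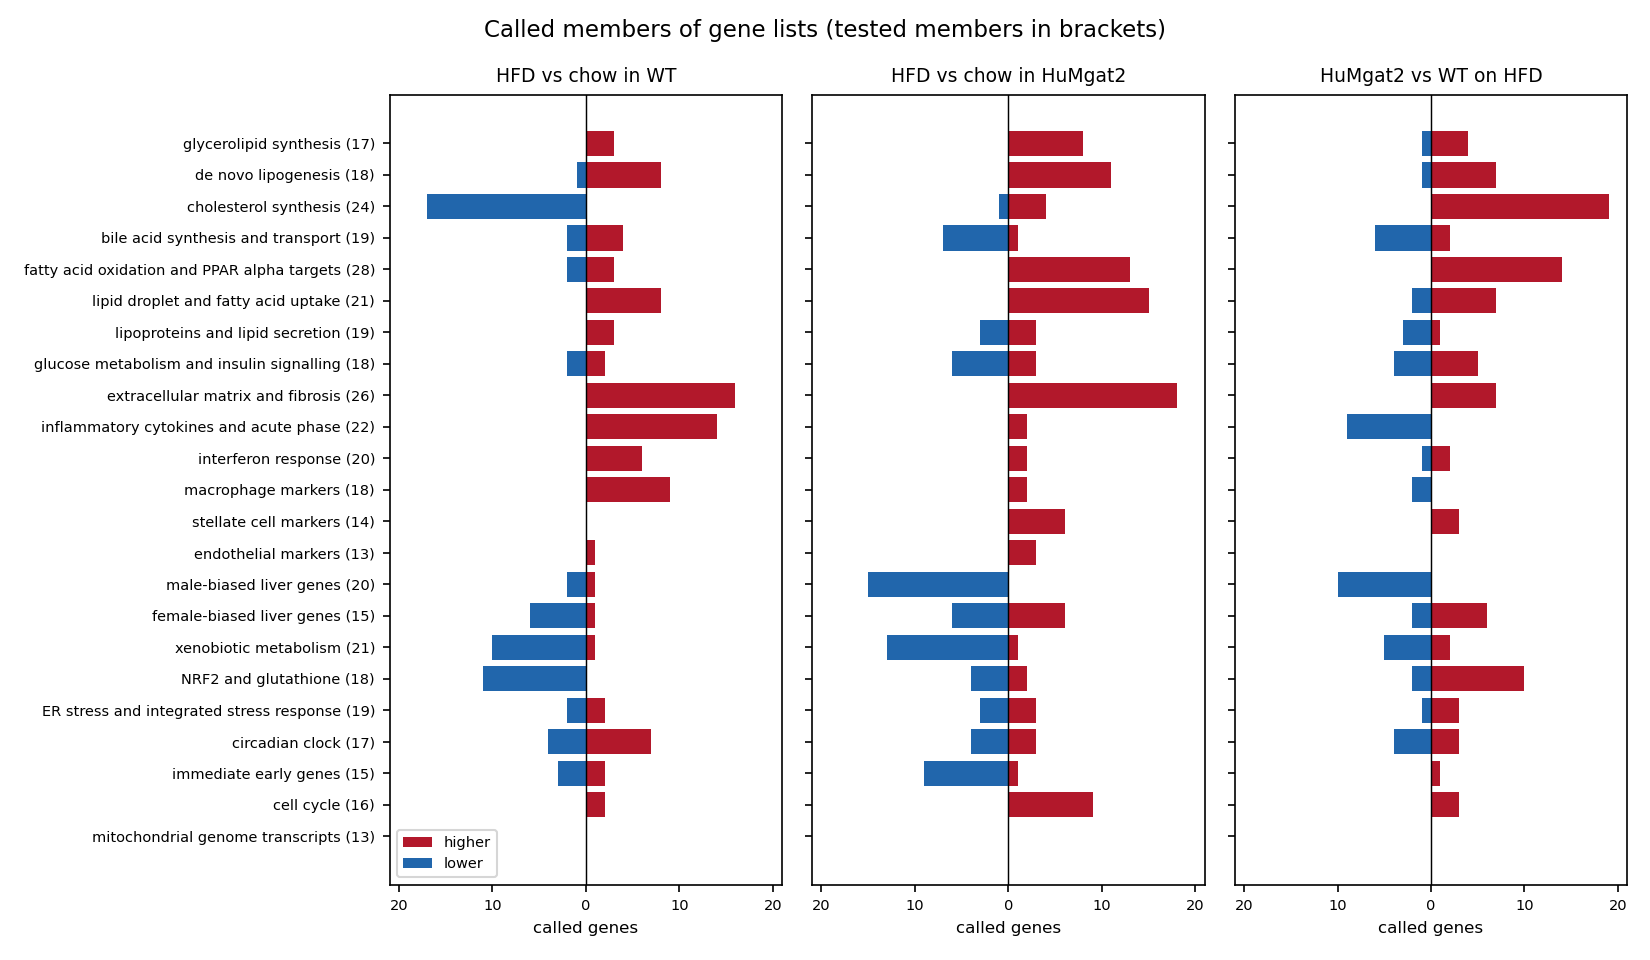
Number of tested members of each gene list that were higher or lower (horizontal axis, bars to the right and left of 0) for lists with at least 10 tested members, in HFD against chow in WT, HFD against chow in HuMgat2, and HuMgat2 against WT on HFD. Cholesterol synthesis had 17 members lower with HFD in WT and 19 higher in HuMgat2 than in WT on HFD, and male-biased liver genes had 15 lower with HFD in HuMgat2.

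The diet effects of both genotypes overlapped. Of the called genes 342 were higher with HFD in both WT and HuMgat2, where 109.5 would be expected for independent sets (odds ratio 4.8, two-sided Fisher's exact test p = 6.25e-91). Another 312 were lower in both, against 74.8 expected (odds ratio 7, two-sided Fisher's exact test p = 2.08e-118), and 93 moved in opposite directions. Both comparisons share the estimate of the spread of each gene, and genes are not independent. The expected counts and these p may therefore be too low. Col3a1, Apoa4, Mmp12 and Themis were among those higher in both, and Cyp2b10, Cyp2c55, Cyp3a44 and Slc13a2 among those lower in both. Across genes, which are not independent replicates, Pearson's correlation of the log2 changes was 0.37 and Spearman's 0.35. The number higher in both was 523 without WT HFD library 4.

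On chow, HuMgat2 and WT livers differed little. Nnt (ENSMUSG00000025453 and ENSMUSG00000116207 share the name), the mitochondrial nicotinamide nucleotide transhydrogenase, was 2.68-fold higher in HuMgat2, at 102.6 ± 19.7 against 38.29 ± 4.75 CPM (log2 1.42, adjusted p = 4.57e-05). Camk2b, a calcium-dependent kinase subunit, was 5.79-fold higher, at 17.11 ± 2.41 against 2.947 ± 0.288 CPM (log2 2.53, adjusted p = 8.67e-05). Papss1, which makes the sulfate donor for sulfation, was 2.63-fold lower, at 3.835 ± 0.53 against 10.12 ± 1.43 CPM (log2 -1.39, adjusted p = 6.94e-05). All 4 libraries of one genotype lay beyond the other 4 in these genes. Between the genotypes 88 genes differed on chow, 46 higher and 42 lower in HuMgat2. Of these 87 had no overlap, against 6.6% of all tested genes. The higher count was 27 without WT chow library 5 or HuMgat2 chow library 13, and the lower count was 26 without WT chow library 5. Without WT HFD library 4 there were 204 calls, the 88 among them. Another division of these 8 libraries, WT 5 and 7 with HuMgat2 14 and 16 against the rest, called 179 genes, more than genotype did. In the labels the sample index of each library on the first side is lower than that of every library on the other. What the index stands for is not stated, and it was not fitted.

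The other large increases on chow were in Chic1 (4.08-fold), smooth muscle actin Acta2 (3.47-fold), Zfp791 (2.91-fold), the Notch target Hes1 (2.89-fold), thymidine phosphorylase Tymp (2.71-fold) and Cnbd2 (2.62-fold). The mitochondrial glycine tRNA mt-Tg, with 2 counts over the HuMgat2 chow group and 198 in WT, was 95.2-fold lower (95% counting interval 26 to 792). Rwdd2a (4.78-fold), Epb41l1 (3.06-fold), the transcription factor Elf5 (2.69-fold), Tmem254a (2.67-fold), Plac9a (2.53-fold) and Pcp4l1 (2.22-fold) were also lower. Several of these calls depended on single libraries of the 8. The call of Acta2 ended without any of them but WT chow library 5 and HuMgat2 chow library 13, and that of Plac9a without any but WT chow library 7 and HuMgat2 chow library 14. Pcp4l1 lost its call without any but WT chow library 6, and Tymp without any but HuMgat2 chow libraries 14 and 16. For Rwdd2a the call ended without WT chow library 5 or 6 or HuMgat2 chow library 13, 15 or 16, and for Elf5 without WT chow library 5 or 8 or HuMgat2 chow library 14, 15 or 16. The highest adjusted p was 0.131 for Acta2, 0.11 for Plac9a, 0.133 for Pcp4l1, 0.123 for Tymp, 0.0809 for Rwdd2a and 0.0793 for Elf5.

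The set test called 6 lists on chow, and few of their members changed alone. Matrix genes had 1 of 26 higher, Acta2, and 1 lower, Loxl2 (1.77-fold), with 3 and 1 adjusted over the list alone (adjusted p = 4.7e-05). The call of Loxl2 ended without any library but WT chow library 7 and HuMgat2 chow library 13 (highest adjusted p = 0.121). Immediate early genes had 1 of 15 higher, Btg2 (3.88-fold), which ended without any library but HuMgat2 chow library 15 (highest adjusted p = 0.153), and 7 adjusted over the list alone (adjusted p = 1.59e-05). The interferon list was higher with 0 members called and 2 adjusted over the list alone (adjusted p = 0.0104), and the lymphocyte list was lower with 0 called and 2 adjusted over the list alone (adjusted p = 0.00248). Mitochondrial genome transcripts (adjusted p = 0.0212) and erythroid markers (adjusted p = 0.0423) were higher with 0 called either way. The adjusted p of these 6 lists with an estimated correlation lay between 0.812 and 0.972. No member of any other list was called on chow by edgeR, and their sets had adjusted p between 0.0577 and 0.95. Cell cycle genes, at 0.0577, were called without WT HFD library 4 (adjusted p = 0.0413), but not with an estimated correlation. At an unadjusted p below 0.05, 1863 genes passed in this comparison.

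**Figure D2:**
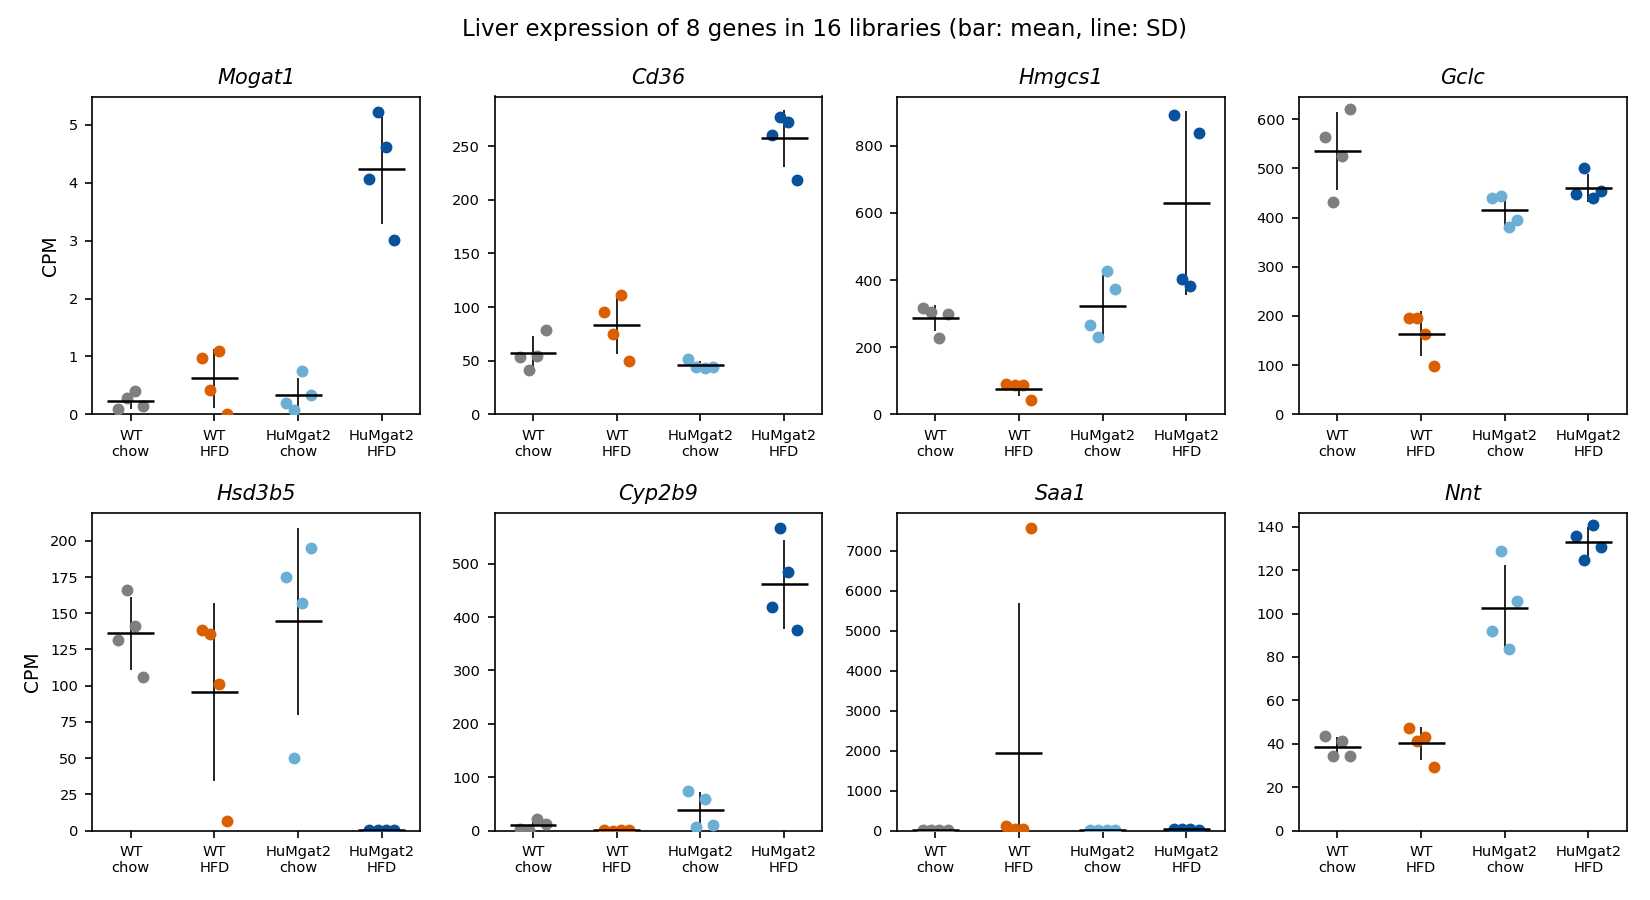
Level of 8 genes in each of the 16 libraries, in counts per M (CPM), one point per library, with the group mean as a bar and the SD as a line, for WT and HuMgat2 mice on chow and HFD. Cd36 reached 257.3 CPM in HuMgat2 on HFD against 82.85 CPM in WT on HFD, Hsd3b5 fell to 0.344 CPM in HuMgat2 on HFD, and Nnt was higher in HuMgat2 on both diets.

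On HFD the genotypes differed widely. In HuMgat2, 19 of 24 cholesterol synthesis genes, 14 of 28 oxidation genes and 10 of 18 NRF2 targets were higher, and 10 of 20 male-biased genes were lower. With all libraries none of these 4 lists was called as a set with an estimated correlation (adjusted p 0.305 to 0.433). Hmgcs1 (ENSMUSG00000093930), which makes HMG-CoA for sterol synthesis, was 8.23-fold higher, at 629.4 ± 274 against 76.36 ± 23.4 CPM (log2 3.04, adjusted p = 1.34e-05). Cyp2b9 (ENSMUSG00000040660, chromosome 7, 25872836 to 25910086), a cytochrome P450 gene higher in female than in male mouse liver, was 4460-fold higher, at 461.4 ± 83.4 against 0.0929 ± 0.105 CPM. Its log2 difference was 12.12 (adjusted p = 4.32e-05), and 13.45 without WT HFD library 3. Complement gene C6 was 5.14-fold lower, at 61.31 ± 21.6 against 315.3 ± 46.7 CPM (log2 -2.36, adjusted p = 6.35e-06). All 4 libraries of one genotype lay beyond the other 4 in these genes. Between the genotypes 2558 genes differed on HFD, 1249 higher and 1309 lower in HuMgat2. Of these 2179 had no overlap, against 21.2% of all tested genes. The higher count was 829 without HuMgat2 HFD library 10, and the lower count was 756, 856 and 872 without HuMgat2 HFD libraries 10, 9 and 11. Leaving out WT HFD library 4 gave 2501 calls, 2001 of the 2558 among them.

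Of 24 cholesterol synthesis genes 19 were higher and 0 lower in HuMgat2 on HFD (22 higher adjusted over the list alone; adjusted p = 4.5e-17), with Idi1 (8.67-fold), Nsdhl (5.06-fold), Cyp51 (5.41-fold) and Sqle (11.9-fold) among them. Of 28 fatty acid oxidation and PPAR alpha genes 14 were higher and 0 lower (17 higher adjusted over the list alone; adjusted p = 2.61e-09), including Pdk4 (5.11-fold), Acot3 (5.21-fold) and Fgf21 (4.6-fold). NRF2 and glutathione genes had 10 of 18 higher and 2 lower (14 and 2 adjusted over the list alone; adjusted p = 1.97e-06), with Gclc 2.81-fold, Srxn1 2.29-fold and Cbr3 10.5-fold higher. Matrix genes had 7 of 26 higher and 0 lower (9 higher adjusted over the list alone; adjusted p = 2.15e-05), Mmp12 (2.81-fold) among them. That count was 11 without WT HFD library 4 and 4 without HuMgat2 HFD library 10. Cell cycle genes had 3 of 16 higher and 0 lower (3 adjusted over the list alone; adjusted p = 0.000102), Cdc20 (3.36-fold) among them, and 9 without WT HFD library 4. Stellate cell markers had 3 of 14 higher and 0 lower (4 adjusted over the list alone; adjusted p = 0.0034), Lrat (1.71-fold) and Dcn (1.48-fold) among them. With an estimated correlation the adjusted p of these 6 lists was 0.305, 0.433, 0.305, 0.433, 0.433 and 0.433.

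Fat-handling lists were higher in HuMgat2 on HFD, though WT HFD library 4 decided their set tests. Lipid droplet and uptake genes had 7 of 21 higher and 2 lower (8 and 3 adjusted over the list alone; adjusted p = 0.00118, and 0.0697 without WT HFD library 4). Cd36 was 3.1-fold, Cidea 16.1-fold and Plin4 3.4-fold higher, and Lpl was 2.03-fold lower. The log2 difference of Cidea was 4.01, and 5.08 without WT HFD library 2. De novo lipogenesis had 7 of 18 higher and 1 lower (10 and 3 adjusted over the list alone; adjusted p = 0.0318, and 0.229 without WT HFD library 4). Its count of higher members was 3 without WT HFD library 1, 2 or 4 or HuMgat2 HFD library 10 and 4 without HuMgat2 HFD library 12. ATP citrate lyase Acly (2.88-fold), malic enzyme Me1 (3.4-fold) and Pklr (2.23-fold) were higher, and Srebf1 was 1.84-fold lower. Glycerolipid synthesis had 4 of 17 higher and 1 lower (4 and 2 adjusted over the list alone; adjusted p = 0.0212, and 0.0981 without WT HFD library 4), with Mogat1 and Gpam (2.15-fold) among the higher and Dgat2 the lower one. With an estimated correlation the adjusted p of these 3 lists was 0.433, 0.664 and 0.433.

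Of the sex-biased lists on HFD, the male-biased one was lower and the female-biased one went both ways. Male-biased liver genes had 10 of 20 lower and 0 higher in HuMgat2 (14 lower adjusted over the list alone; adjusted p = 4.85e-05), and 15 lower without WT HFD library 4. Besides C6, Hsd3b5 was 273-fold and Slco1a1 19-fold lower, the latter with a log2 difference of -4.25 that was -5.01 without HuMgat2 HFD library 9. Female-biased genes had 6 of 15 higher and 2 lower (6 and 3 adjusted over the list alone; adjusted p = 0.00894, and 0.398 without WT HFD library 4, where 6 were higher and 4 lower), with a median log2 difference of 0.10 against a mean of 1.99. Among those higher was Hao2 (131-fold), a peroxisomal hydroxy acid oxidase, beside Cyp2b9. Both lists had adjusted p = 0.433 with an estimated correlation. The labels do not give the sex of the mice. Of 14 tested genes on chromosome Y, edgeR called 0 between genotypes on either diet. DESeq2 called 2 of the 14 on either diet, and 1 on chow.

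Inflammatory genes were lower in HuMgat2 on HFD, with 9 of 22 lower and 0 higher (13 lower adjusted over the list alone; adjusted p = 0.0212). Without WT HFD library 4 there were 3 lower and 2 higher, and the set test gave adjusted p = 0.963. Without HuMgat2 HFD library 10 there were 5 lower. The calls of Saa1 (log2 -5.97) and Saa2 (log2 -6.84) ended without WT HFD library 4, at -0.94 with adjusted p = 0.152 and -0.30 with adjusted p = 0.636. Lymphocyte markers had 3 of 7 lower and 0 higher (3 adjusted over the list alone; adjusted p = 0.0338, and 0.0697 without WT HFD library 4), Cd4 (5.39-fold) among them, and 5 lower without WT HFD library 1. Erythroid markers had 3 of 6 higher and 0 lower (4 adjusted over the list alone; adjusted p = 0.00896), with the globin Hba-a1 4.17-fold higher. The erythroid count was 0 without WT HFD library 3 or HuMgat2 HFD library 10, where Hba-a1 had adjusted p = 0.0518 and 0.0887. Endothelial markers had 0 of 13 called, with a set test of adjusted p = 0.0452, and 0.107 without WT HFD library 4. With an estimated correlation the inflammatory list had adjusted p = 0.71 and the lymphocyte, erythroid and endothelial lists 0.433.

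The remaining lists were not called as sets on HFD (adjusted p between 0.0743 and 0.987). Bile acid genes had 2 of 19 higher and 6 lower, with Cyp2c70 5.16-fold and Abcg5 4.15-fold lower. Xenobiotic genes had 2 of 21 higher and 5 lower, with Cyp2c38 4.44-fold higher and Cyp1a2 5.18-fold lower. The lipoprotein list had 1 of 19 higher and 3 lower, the lipoprotein receptor Scarb1 (2.13-fold) and the cholesterol exporter Abca1 (1.75-fold) among the lower. Glucose and insulin signalling had 5 of 18 higher, Irs1 (1.61-fold) among them, and 4 lower, with Igfbp2 (4.68-fold) and Irs2 (2.26-fold). The higher count was 3 without WT HFD library 4 or HuMgat2 HFD library 11 or 12. Clock genes had 3 of 17 higher, with Npas2 11.8-fold, and 4 lower, with Bhlhe41 4.38-fold. Their lower count was 2 without HuMgat2 HFD library 9, 10 or 11 and 7 without library 12. Stress response genes had 3 of 19 higher, Atf5 (2.31-fold) among them, and 1 lower, Xbp1 (1.79-fold). Interferon genes had 2 of 20 higher and 1 lower, and immediate early genes 1 of 15 higher. Macrophage markers had 2 of 18 lower, and 3 higher with 0 lower without WT HFD library 4. Of 3 adipocyte markers 1 was higher and 1 lower, Cfd (14.1-fold). None of 8 cholangiocyte, 13 mitochondrial genome, 1 pancreas or 1 neutrophil members was called. Leaving out WT HFD library 4 led to a call as lower of the bile acid list (adjusted p = 0.0183) and the xenobiotic list (0.00182), each with 7 members lower. Neither was called with an estimated correlation.

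Among the largest differences on HFD without overlap, Cyp2b13 had 2 counts over the WT group and 4129 in HuMgat2, a 1810-fold difference (95% counting interval 502 to 15000). A4gnt was 36.2-fold higher (log2 5.18, and 6.30 without WT HFD library 3), Gprc5b 25.3-fold, the fatty acid hydroxylase Cyp4a14 21.6-fold, the transporter Slc22a27 20.9-fold and the phosphate transporter Slc34a2 17.8-fold. Moxd1 had 1 count over the HuMgat2 group and was 5090-fold lower (95% counting interval 912 to 201000). Igkv8-16 was 1810-fold (325 to 71700), Prtn3 344-fold (94.7 to 2840), mt-Tg 250-fold (44.5 to 9930) and Hsd3b4 129-fold (35.2 to 1070) lower, each with 1 or 2 counts over the HuMgat2 group. The fitted log2 difference of Prtn3 was -8.66, and -5.18 without WT HFD library 4. Adgrf1 was 55.5-fold and the pseudogene Serpina4-ps1 56.6-fold lower (log2 -5.82, and -4.99 without WT HFD library 2). Of the genes named as called in this comparison, Srebf1, Cfd, Hba-a1, Slco1a1, Saa1 and Saa2 had overlapping ranges between the genotypes, and the others did not overlap.

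**Figure D3:**
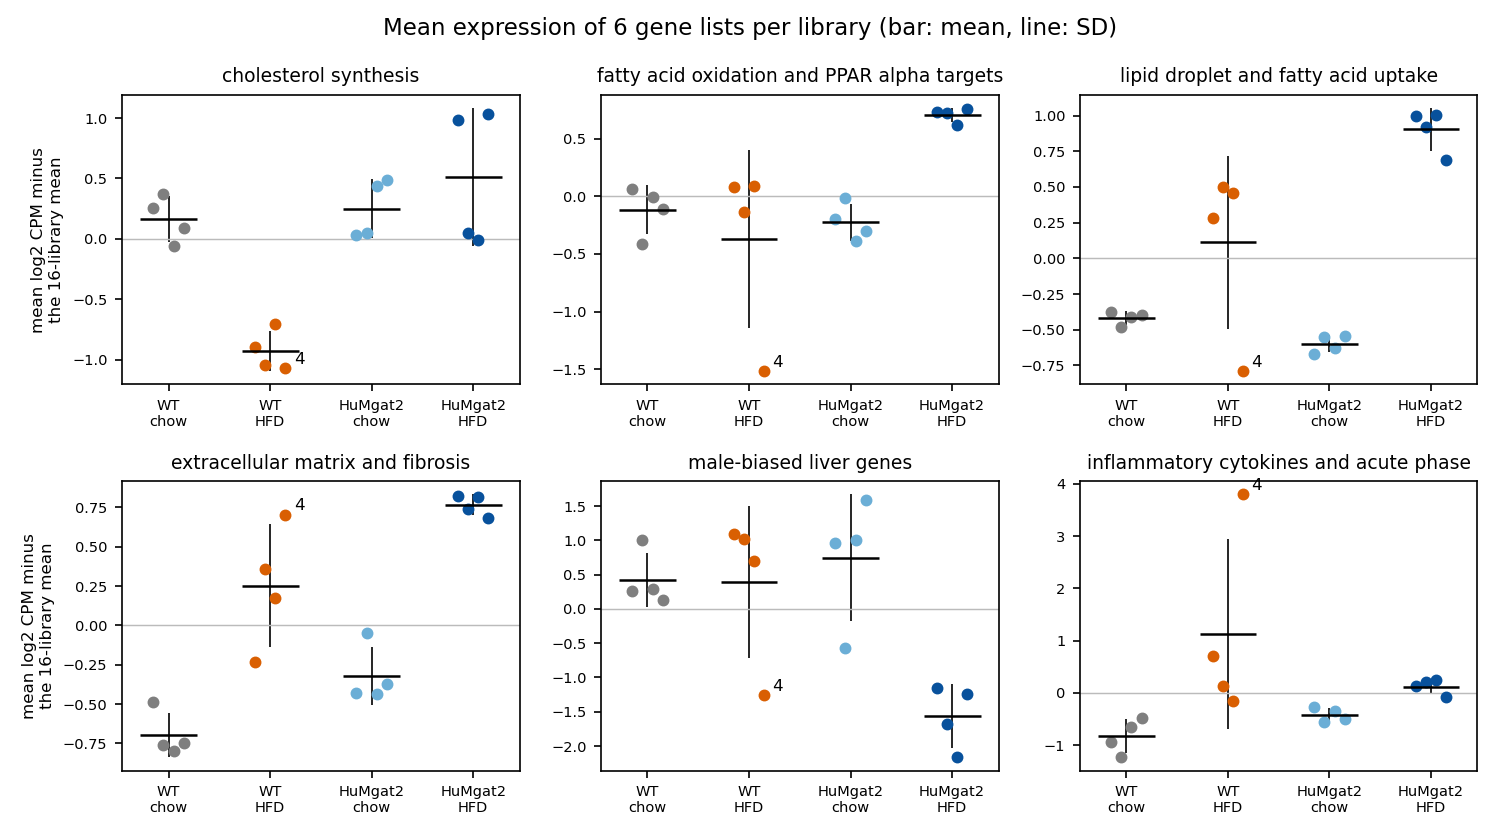
Mean log2 CPM of the members of 6 gene lists in each of the 16 libraries, as the difference from the mean of all libraries (vertical axis), one point per library, by group. The label 4 marks WT HFD library 4.

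The interaction test asked which diet effects differed between the genotypes, and 844 genes were called, 452 with a higher and 392 with a lower diet effect in HuMgat2. The clearest was Slc22a27, an organic anion transporter family member, which fell in WT from 1.835 ± 0.499 to 0.9441 ± 0.33 CPM and rose in HuMgat2 from 1.292 ± 0.082 to 19.85 ± 1.61 CPM (interaction log2 4.90 ± 0.32 SE, adjusted p = 4.79e-07). The fall in WT was not called without WT chow library 5 (adjusted p = 0.0512). Gpcpd1, which releases choline from a glycerophospholipid product, rose in WT from 41.6 ± 3.76 to 244.7 ± 32.7 CPM and stood at 58.44 ± 16.5 and 43.84 ± 13.6 CPM in HuMgat2 (interaction log2 -2.97). Cyp2c70, which makes muricholic acids, rose in WT and fell in HuMgat2 (interaction log2 -2.88, adjusted p = 8.35e-05). The other genes with the smallest adjusted p were the kinase Pim1 (log2 -2.04), Adam11 (-3.24), Cyp2c38 (2.63), UDP-glucose dehydrogenase Ugdh (1.76), Pcp4l1 (3.30), the cadherin Cdh1 (-2.95) and Slc22a29 (3.29). The counts were 284 and 245 without WT chow library 5, 290 and 260 without HuMgat2 chow library 15, and 293 and 258 without HuMgat2 HFD library 10. Without WT HFD library 4, 1129 genes were called, 798 of the 844 among them.

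Of 24 cholesterol synthesis genes 14 had a higher diet effect in HuMgat2 and 0 a lower one (18 higher adjusted over the list alone; adjusted p = 4.38e-14), and 8 without HuMgat2 HFD library 10. Hmgcs1 (2.87), Idi1 (3.15), Nsdhl (2.31) and Sqle (3.66) were among them, as log2 differences. Fatty acid oxidation and PPAR alpha genes had 5 of 28 higher and 0 lower (12 higher adjusted over the list alone; adjusted p = 3.76e-08), Pdk4 (2.56) and Fgf21 (3.10) among them, and 12 without WT HFD library 4. NRF2 and glutathione genes had 5 of 18 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 5.49e-06), Gclc (1.86) among them, and 8 without HuMgat2 chow library 14. Male-biased genes had 7 of 20 lower and 0 higher (13 lower adjusted over the list alone; adjusted p = 7.99e-06), Hsd3b5 (-8.18) among them, with 14 without WT HFD library 4 and 12 without HuMgat2 chow library 14. Lipid droplet genes had 4 of 21 higher and 0 lower (8 and 2 adjusted over the list alone; adjusted p = 0.00033), with Cd36 (1.95) and Plin4 (3.21). With an estimated correlation these 5 lists had adjusted p = 0.475, 0.541, 0.475, 0.541 and 0.541.

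Another 8 lists passed the set test of the interaction less clearly, and 0 of the 13 called did so with an estimated correlation. A higher diet effect in HuMgat2 was found for stellate cell markers (1 of 14, adjusted p = 0.00918), glycerolipid synthesis (1 of 17, adjusted p = 0.0138), de novo lipogenesis (1 of 18, adjusted p = 0.0254) and cell cycle genes (0 of 16, adjusted p = 0.0308). Female-biased genes had 4 of 15 higher (adjusted p = 0.0265), with a median log2 difference of -0.03 against a mean of 1.58, the 1 called list of the 58 in all comparisons whose median, mean and test differed in sign. Among the 135 tests 25 differed so. A lower diet effect was found for inflammatory genes (4 of 22, adjusted p = 0.0103), immediate early genes (3 of 15, adjusted p = 0.0254) and bile acid genes (6 of 19, adjusted p = 0.0303). The inflammatory count was 2 without any WT chow library, HuMgat2 chow library 15 or HuMgat2 HFD library 9, 10 or 11, and 7 without WT HFD library 2 or 3. Leaving out WT HFD library 4 ended the set calls of inflammatory genes (adjusted p = 0.384), immediate early genes (0.135), de novo lipogenesis (0.222) and female-biased genes (0.646, with 3 higher and 4 lower). It led to calls of matrix genes as higher (0.0134) and of xenobiotic (0.00238), clock (0.0227) and mitochondrial genome genes (0.0111) as lower. With an estimated correlation none of these lists was called in that fit either.

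The last question was whether genes that differ by genotype sit near the modified locus. In a window of 20 Mb centred on Mogat2, 29 of 182 tested genes (15.9%) were called between genotypes on either diet by edgeR, against 15% elsewhere (two-sided Fisher's exact test p = 0.677), and 0 were called on chow. DESeq2 called 2 of the 182 on chow and 36 (19.8%) on either diet, against 18.6% elsewhere. By chromosome, genes called on chow were enriched on chromosome 14, with 15 of 605 tested (odds ratio 5.79, two-sided Fisher's exact test, adjusted p = 7.81e-06), and on chromosome 4, with 14 of 1038 (odds ratio 2.99, adjusted p = 0.00782). Both rested on 1 cluster of genes each, on chromosome 14 with pairs of equal counts such as Gm38378 and Gm37513, so these genes are not independent. Without the 33 tested genes of the clusters, 5 of 589 were called on chromosome 14 and 8 of 1021 on chromosome 4, and neither was enriched (adjusted p = 0.551 for each). With DESeq2 calls and the clusters kept, adjusted p was 2.18e-05 for chromosome 14 and 0.42 for chromosome 4. Genes called on either diet were enriched on chromosome 3, with 175 of 918 (odds ratio 1.36, adjusted p = 0.0134). On both diets 51 genes were called by genotype, 39 of them in the same direction, 13 higher and 26 lower, where 3.3 and 3.2 would be expected for independent sets, and 12 in opposite directions. Nnt, Zfp791 and Tymp were higher on both diets, and Papss1, Tmem254a, Plac9a, Elf5 and mt-Tg lower.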

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

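The test of chow genes in the HFD libraries was chosen only after the results were seen, and the divisions of libraries into other groups before. The real division of the libraries called more genes than any other for HFD against chow in WT (1 of 35, highest other 14), for the same in HuMgat2 (1 of 35, highest other 3), for genotype on HFD (1 of 35, highest other 14) and for the interaction (1 of 100, highest other 2). The divisions for the interaction exchanged genotype labels within each diet. They therefore cannot separate an interaction from a genotype difference. For genotype on chow 2 of 35 divisions called as many, one of them 179, so the number of calls there does not exclude chance. Outside the clusters of copies on chromosomes 14 and 4, 24 of the chow genes, Nnt among them, were called in the same direction in the separate HFD libraries. For independent sets 5.2 would be expected (two-sided Fisher's exact test p = 1.47e-05 for those higher and 1.04e-06 for those lower). Both comparisons share 1 estimate of the spread per gene, and genes are not independent, so 5.2 and these p may be too low. The other 48 were not called in the same direction, and 12 of them were called in the opposite one. How many of the chow calls chance accounts for stays open. Of those 179 genes 0 were called by genotype, 110 were higher and 69 lower in WT chow libraries 6 and 8 with HuMgat2 13 and 15, whose mitochondrial share was 6.254% to 13.654% against 5.507% to 5.925%, and 4 mitochondrial transcripts were among those higher.

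Dixon's ratio, the gap to the nearest library over the range, marked single libraries in 40 of 512 group values, where 25.6 are expected by chance. The values were total counts, albumin and mitochondrial shares, and the CPM of 125 genes named in the text. These genes are not independent, and many were named for large changes in the same libraries, WT HFD library 4 included. The 25.6 is therefore only a rough guide. Of the 40 marked, 12 were in WT on HFD and 10 were WT HFD library 4. The latter was highest for Saa2 (0.996), Saa1 (0.987), Lcn2 (0.96), Prtn3 (0.979), Gpnmb (0.944), Rad51b (0.992), Pcp4l1 (0.914) and Pim1 (0.829), and lowest for Hmgcs1 (0.905) and Papss1 (0.929). WT HFD library 3 was highest for Cyp2b13 (1) and Gpcpd1 (0.958). In WT on chow the mitochondrial share (0.852) and Elf5 (0.843) were highest in library 8, Moxd1 (0.99) and Cyp2c70 (0.924) in library 6 and Acta2 (0.865) in library 5, where Isg15 (0.887) was lowest. In HuMgat2 on chow library 14 was highest for Abcg5 (0.913), Gprc5b (0.947) and Acly (0.852) and lowest for Thrsp (0.881), Slco1a1 (0.855) and Cyp2c53-ps (0.907). Library 15 was highest for Fasn (0.854) and mt-Tg (1) and lowest for Cyp3a44 (0.92), library 16 highest for Moxd1 (0.921) and C6 (0.839), and library 13 for Cd36 (0.916). In HuMgat2 on HFD library 9 was highest for Moxd1 (1), Cyp2c55 (0.897) and Hsd3b4 (1) and lowest for Acta2 (0.844). Library 10 was highest for Irs1 (0.862) and mt-Tg (1), library 11 for Igkv8-16 (1) and Rwdd2a (0.903), and library 12 for Slc13a1 (0.889) and Dusp1 (0.855). The ratios of 1 rest on 1 or 2 counts in a group. In the voom fit WT HFD library 4 had a weight of 0.23.

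The diet effect was higher in HuMgat2 for 452 genes and lower for 392. Of the genes named in the text 65 were among them, 35 higher and 30 lower, given here as log2 differences. Of sterol synthesis and relatives these were Sqle 3.66, Idi1 3.15, Idi1-ps1 3.16, Cyp51 2.44, Hmgcs1 2.87 and Nsdhl 2.31. Lipid genes were Pdk4 2.56, Acot3 2.85, Fgf21 3.10, Cyp4a14 5.63, Cd36 1.95, Plin4 3.21, Gpam 1.26, Me1 2.12, Scarb1 -0.91, Abca1 -0.67, Abcg5 -2.49, Cyp2c70 -2.88 and Gpcpd1 -2.97. Antioxidant and stress genes were Gclc 1.86, Srxn1 1.19, Cbr3 3.80, Atf5 1.10 and Xbp1 -1.12. Clock, insulin and early genes were Npas2 3.85, Per3 -1.06, Bhlhe41 -2.98, Irs1 0.97, Irs2 -1.24, Igfbp2 -1.72, Ier2 -2.12 and Btg2 -2.62. Sex-biased and steroid genes were Hsd3b5 -8.18, Slco1a1 -4.09, C6 -2.42, Cyp2b9 10.16 and Hao2 6.29. Hsd3b4 (-7.05, and -9.26 to -6.58 without single libraries) and Moxd1 (-14.67, and -19.69 to -11.53) had 2 counts and 1 over the HuMgat2 HFD group, so their sizes are fitted values only. The Moxd1 counts in HuMgat2 on chow rest on library 16 (29.21 CPM, others at most 2.309), and its diet call in HuMgat2 ended in 5 of 8 fits without single libraries. Xenobiotic and transport genes were Cyp1a2 -2.54, Cyp2c38 2.63, Cyp2c53-ps -4.52, Ugdh 1.76, Slc22a27 4.90, Slc22a29 3.29 and Slc34a2 3.31. The others were Saa1 -7.38 (-2.35 without WT HFD library 4), Cd4 -3.31, Csad 2.49, Adgrf1 -6.29, Lrat 1.13, Loxl2 1.05, Camk2b -1.89, Chic1 -1.84, Hes1 -1.18, Cnbd2 -2.12, Rwdd2a 3.61, Epb41l1 1.95, Papss1 0.82, Pcp4l1 3.30, Gprc5b 4.15, Serpina4-ps1 -4.84, Pim1 -2.04, Adam11 -3.24 and Cdh1 -2.95. Leaving out single libraries ended the interaction call in 8 of 16 fits for Saa1 and Per3, 11 for Csad and Gpam, 10 for Papss1, 6 for Lrat, 4 for Me1 and 1 for Serpina4-ps1, with a highest adjusted p of 0.0984, for Csad. Their causes were not tested.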

How the results depend on the processing

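The voom setting and the fits read without WT HFD library 4 as comparisons of their own were chosen only after the results were seen. With only the 2 groups compared in the fit, HFD against chow in WT had 655 genes higher and genotype on HFD 854 lower. With DESeq2, genotype on chow had 133 higher and 105 lower. With limma voom and sample quality weights, 1902 genes were lower with HFD in WT, 77 were higher by genotype on chow, 2176 higher and 2147 lower by genotype on HFD, and 754 higher and 637 lower in the interaction. By voom the genotype difference of Lcn2 on HFD was 0.67 (adjusted p = 0.375) against -3.70 (adjusted p = 0.0325) in edgeR; its adjusted p ran up to 0.977 over the alternatives, without WT HFD library 4. The causes of these shifts were not tested. Leaving out 1 library at a time gave 856 to 1522 higher and 817 to 1237 lower with HFD in WT, 947 to 1291 and 679 to 1046 in HuMgat2, 27 to 63 and 26 to 57 by genotype on chow, 829 to 1303 and 756 to 1403 on HFD, and 284 to 600 and 245 to 529 in the interaction. Genes with a diet effect shared by both genotypes numbered 237 to 523 higher and 208 to 409 lower. The correlation of diet effects ran from 0.33 to 0.38, and the genes in the window from 20 to 31, with 36 by DESeq2 and 11 and 54 in windows of 10 and 40 Mb. Among named calls DESeq2 kept 324 of 324 with an adjusted p and gave none for 12, its size factors 336 of 336, no filter 332 of 336, 1 CPM 328 of 330, leaving out mitochondrial, ribosomal and hemoglobin genes 331 of 333, 2 groups alone 234 of 261 and voom 316 of 336, with 1 reversed. The set test called 58 of 135 lists with both scalings and 0 with an estimated correlation (lowest adjusted p = 0.189), against 59 and 6 without WT HFD library 4, where 47 of the 58 were kept. Leaving out the gene clusters ended the enrichment on chromosomes 14 and 4.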

Other observations

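The tests on WT HFD library 4, on the genes that differ on both diets and on the clock genes were chosen only after the results were seen. The clock genes of the liver moved with diet in ways the list test did not sum up. In WT on HFD Arntl, Clock and Npas2 fell while Dbp, Tef, Per3 and Ciart rose, but Nr1d1, of the same arm as Per3, fell (log2 -0.95, adjusted p = 0.0278) and Nr1d2 was not called (adjusted p = 0.249). In HuMgat2 on HFD Npas2 was 11.8-fold above WT and Bhlhe41, which represses clock genes, 4.38-fold below it. The difference between 3 genes of one arm of the clock and 6 of the other was -1.56 ± 0.44 (log2, SD, n = 4) in WT on chow, -4.46 ± 0.74 in WT on HFD, -1.90 ± 0.21 in HuMgat2 on chow and -2.69 ± 1.01 in HuMgat2 on HFD.

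Cholesterol synthesis genes were higher in HuMgat2 on HFD, and 18 of the 19 calls, Hmgcs1 and Idi1 among them, were kept without WT HFD library 4, so that library does not account for them. These genes could follow collection time or feeding, since both sterol and clock genes vary over the day. The clock arms differed by 1.77 log2 units between HuMgat2 and WT on HFD, with an exact permutation p = 0.0571 over 70 divisions of the libraries, and neither time nor feeding is in the labels. A genotype effect on sterol synthesis and a difference in collection time or feeding cannot be told apart here. Hours of collection, or sterol levels in the same livers, would separate them. The fall of sterol synthesis genes with HFD in WT is under the same limit. The clock arm difference in WT was -1.56 ± 0.44 on chow and -4.46 ± 0.74 on HFD (log2, SD, n = 4).

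The 39 genes that differed by genotype in the same direction on both diets, such as Nnt, Papss1, Tymp and mt-Tg, may mark a difference in strain or colony background. Of these genes 0 lay in the window on Mogat2, so they do not themselves lie in sequence carried beside the modified locus. Whether such sequence acts on genes elsewhere was not tested. The clusters of copies on chromosome 14 (69515050 to 69920735) and chromosome 4 (41893388 to 42244913) held 9 and 6 of the 39 genes. The other 24 lay outside these clusters, on 13 chromosomes. Whether reads of those 24 are shared with copies elsewhere was not tested. Of the 39, 3 had a called interaction, and background cannot be told apart from an effect of the human gene. Background goes with every HuMgat2 library, so the same holds for the 2558 genes called by genotype on HFD and the 844 interaction calls. A deletion in Nnt is known in C57BL/6J mice, which is in line with a background difference, and genotyping of the colonies would settle it.

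WT HFD library 4 might be thought a shallow library or one swapped with a HuMgat2 HFD library. The tests argue against both, while a single wrong label stays open and a swap with a chow library was not tested. Other libraries of its group thinned to 12.4 M counts kept a lowest Spearman correlation of 0.979, against 0.953 at most with library 4. Such a swap needs a partner, but by genotype genes chosen without each library at most 1 gene (of 25) was nearer to WT in any HuMgat2 HFD library. In library 4 itself 29 of 40 were nearer to WT, short of the 32 set for excluding a HuMgat2 liver. Saa1 was at 7570 CPM against 123 at most, and the fibrinogen genes Fga, Fgb and Fgg with Itih4 and Lbp, acute phase genes of hepatocytes looked at only for this test, had a median log2 ratio of 2.03 (SD 0.21), all 5 above the other libraries. This argues against an admixture of other cells as the source of the acute phase genes, taking these 5 as made by hepatocytes, which was not measured. An admixture of immune cells beside them stays open, with Cd74 at 2.95 and Ptprc at 2.19. Alb was at -2.13 and Cfd at -8.55. An inflamed or ill animal is consistent with these values and was not tested.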
